A study of Mus musculus with 50 samples.

How the data were processed

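Mouse B cells activated overnight with LPS were profiled by m6A-seq in 12 libraries: IP and Input for each of 2 Mettl3 genotypes, in 3 replicates each. Per the labels' protocols, polyadenylated RNA was barcoded and taken through 2 rounds of immunoprecipitation with an antibody to m6A. The groups and replicate numbers were taken from the sample labels. The labels do not say whether replicates came from separate mice, so the authors' p-values may measure technical spread only. The 38 expression libraries of germinal center B cells were not analysed here.

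The data were the authors' table of de novo peaks and their table of METTL3-dependent peaks. Per the submitters' processing notes the series used cutadapt, STAR, HTSeq, SAMtools 1.3.1 and DESeq2, with genome builds mm10 and mm9; which step each served is not given in the sources used here, nor are the peak caller and the test behind the p-values. Per the file headers, each peak has a genomic position, a transcript, a position in that transcript, a transcript part, a distance to a consensus motif and a number of peaks per arm, which runs from 0 to 3 and is read here as the number of replicates with the peak called. The peak score is the authors' own value, deposited as 1 pooled number per arm in 2 versions, each with a test minus control difference. The deposited p-value of that difference is unadjusted and given once per version; 137 peaks had none on the first version. The headers name the arms test and control with no genotype. The test arm was read as Mettl3 flox/+ because peaks of the METTL3-dependent table score higher there.

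Positions ran past the ends of 7 GRCm38 chromosomes for 164 peaks. They are therefore not on mm10, which is GRCm38, and were taken as mm9, the other build the processing notes name. The reference genome used here was GRCm38, so no sequence or annotation was drawn from it and no position was converted. None of the 14219 transcript identifiers matched the name tables used here, so the gene lists and the rule for named genes fixed before the data were examined (the deleted genes, the strongest losses, the highest scores, the transcripts with most listed peaks and up to 4 members of each list) could not be applied. In their place, the 2 peaks with the largest and the 2 with the most negative first-version difference are given.

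The design fixed before the data were examined held a test per peak from values per library. As the scores are pooled per arm, no such test was made here, and the authors' list, scores and p-values are described instead. The list was matched to the full table by position and transcript: all 9005 listed peaks were found. The rule behind the list was found by comparing listed and other peaks. Benjamini-Hochberg adjustment was applied to the authors' p-values within each score version.

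Shares have exact Clopper-Pearson 95% intervals, and a share of 0 has the limit of 3 counts of the total. Listed and other peaks were compared by two-sided Fisher's exact tests for each of the 5 transcript parts as the table annotates them, for the first 100 nt and for a motif within 50 nt, with adjustment over the parts. Odds ratio intervals came from 1000 bootstrap draws of whole transcripts, since the Fisher tests treat peaks as independent and their p-values are then too small. Mantel-Haenszel odds ratios over the parts were given for the motif and for the X chromosome, with intervals from the same kind of draws. Transcript-start peaks were compared with the rest by two-sided permutation tests of the medians with 100000 resamples, which treat peaks as exchangeable. The planned permutation test of listed against other peaks' scores was set aside, since the list is chosen on those scores. The 8 peaks with no motif distance were left out of motif comparisons. The table gives no read counts, so depth per library is unknown, and no precision from depth could be set on a score.

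Alternatives were stricter and laxer p thresholds, each score version alone, both together, other windows, peaks with higher scores, the strongest peak of each transcript, merged peaks and sets without the transcript start. The strength of a peak was the mean of both arms' first-version scores. Counts of peaks were called similar when within 1.5 times of each other, and other values with no test when inside the 95% interval of the value they were set against (exact for shares, bootstrap for the median and the mean). Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

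The computations were tested on simulated tables of 32009 peaks. With no change between arms and an SD of 0.6 per replicate, the list rule took 3585 peaks and its opposite 3659. With 6714 peaks changed by a difference of 2, the rule recovered 99.3% of them and also took 11.2% of the unchanged peaks. The observed first-version differences of listed peaks had a median of 0.86 (quartiles 0.40 to 1.36), below the simulated 2; with simulated differences of 1 and 0.5 the rule recovered 70.4% and 34.0% of the changed peaks. The SD was chosen for the simulation, as the spread between replicates is unknown. The simulated score versions varied independently, whereas the observed differences of the 2 versions had a Pearson correlation of 0.715 (Spearman 0.702) across peaks, which are not independent replicates.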

Results

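The samples were B cells of mice bred for deletion of genes for a writer or readers of N6-methyladenosine (m6A), and of control mice. m6A is a methyl mark on adenosines inside messenger RNA; METTL3 is the catalytic subunit of the complex that writes most of it. Of the 50 samples, 12 were m6A-seq libraries in 4 groups of 3. B cells were activated overnight with LPS, a bacterial cell wall component that drives B cells to divide. For each genotype, RNA pulled down with an antibody to m6A (IP) was set against the RNA before pull-down (Input). The genotypes were Mettl3 flox/+ and Mettl3 flox/flox, both carrying AIDcre, a recombinase expressed from the locus of the enzyme AID, which B cells switch on when activated. How much METTL3 the flox/flox cells had lost after overnight LPS was not measured here. Peaks outside the list may therefore include some that depend on METTL3. The series' design text speaks of wild type cells for the m6A profile, whereas the sample labels give these genotypes, which are used here. The other 38 samples were expression libraries from germinal center B cells in 12 groups, with deletions of Mettl3, Ythdf2 or Igf2bp3, and were not analysed here.

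The m6A data were read from the authors' table of 32009 peaks on 14219 transcripts and from their shorter list of METTL3-dependent peaks. Each peak had 1 pooled score for a test arm and 1 for an arm the table calls control, in 2 score versions. The table does not say which genotype is which arm. Because the list is named for METTL3 dependence and holds peaks that scored higher in the test arm, the test arm is read here as the flox/+ cells and the other, called the comparator arm, as the flox/flox cells. All directions between genotypes rest on that reading. The scores are the authors', and their formula and scale are not given in the sources used here, so differences are in score units. No value per library and no read total was used, so the depth is unknown and no spread between replicates can be given for a single peak.

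The first question was how many of the peaks the authors placed in their METTL3-dependent list. That share follows from the rule of the list, given below, and does not measure how much m6A depends on METTL3. The METTL3-dependent list held 9005 peaks, 28.1% of the 32009 (exact Clopper-Pearson 95% interval 27.6% to 28.6%). These lay on 6077 of the 14219 transcripts, or 42.7% (41.9% to 43.6%). Across all peaks the median score was 2.19 in the test arm and 1.94 in the comparator arm, with a median difference per peak of 0.25 (quartiles -0.31 to 0.83). On the second score version the medians were 3.19 and 2.66 and the median difference was 0.49 (-0.12 to 1.06). The test arm was higher in 61.7% of peaks on the first version and in 70.0% on the second. The intervals cover counting error only, and peaks of the same transcript are not independent.

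The list followed 1 rule in all 32009 peaks: an unadjusted p under 0.1 on either score version together with a higher test arm on either version. The opposite rule, with the comparator arm higher, was met by 3430 peaks (10.7%). The rule gave 4533 peaks on the first version alone, 6806 on the second alone and 2794 on both at once. No peak reached a Benjamini-Hochberg adjusted p of 0.05 when the authors' p-values were adjusted over all peaks, the smallest adjusted values being 0.249 and 0.0516 on the 2 score versions. Without adjustment, 3675 of 31872 peaks (11.5%) had a p under 0.05 on the first version and 4778 of 32009 (14.9%) on the second. The list is therefore described below as a set, and membership of a single peak is not a call that passed correction. The name METTL3-dependent peaks stands below for listed peaks.

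The second question was where in the transcript the METTL3-dependent peaks lay. They were most frequent around the stop codon, where 3168 of 6767 peaks were listed (46.8%, 45.6% to 48.0%), and in the 3' UTR, where 2061 of 5550 were (37.1%, 35.9% to 38.4%). The coding sequence held the most peaks, 11623, of which 3033 were listed (26.1%, 25.3% to 26.9%). In the 5' UTR beyond the transcript start, 214 of 1205 were listed (17.8%, 15.6% to 20.04%). At the transcript start, the part that covers about the first 200 nt, 529 of 6864 were listed (7.71%, 7.09% to 8.36%). The stop-codon part thus gave 35.2% of the listed peaks and 15.6% of the others, and the transcript start gave 5.87% of the listed peaks and 27.5% of the others.

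**Figure D1:**
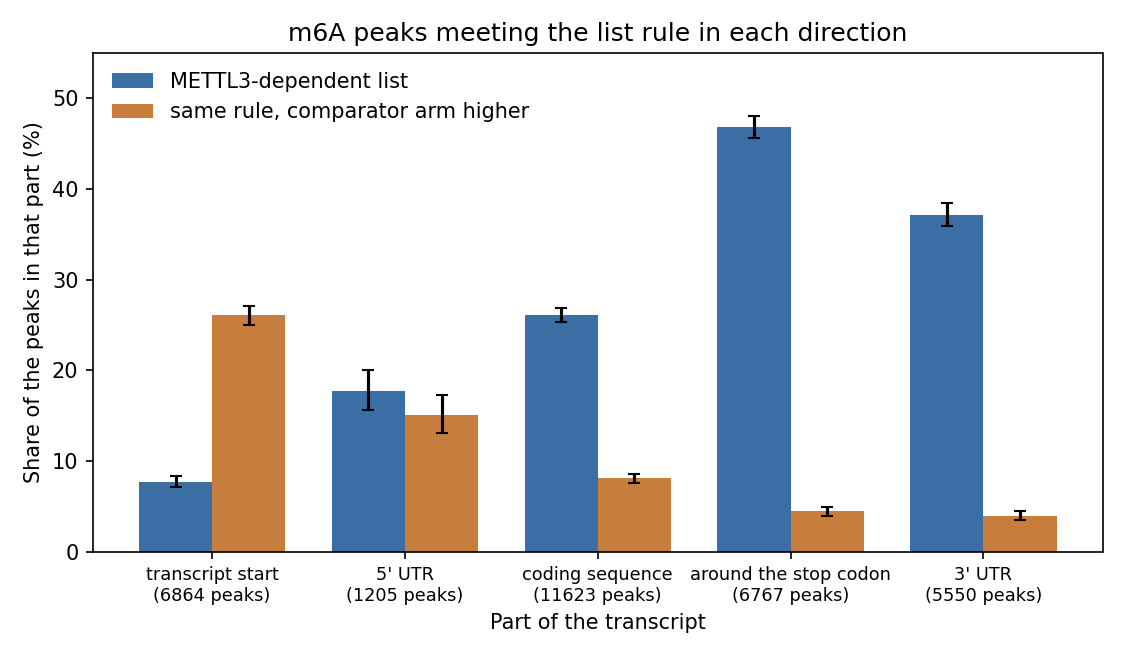
Bars give the percent of the peaks in each transcript part (horizontal axis, with the number of peaks) that are in the METTL3-dependent list, or that meet the same rule with the comparator arm higher; error bars are exact 95% intervals. The listed share runs from 7.71% at the transcript start to 46.8% around the stop codon, while the opposite rule is met by 26.0% of transcript-start peaks and 3.95% of 3' UTR peaks.

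Listed against other peaks, the odds ratio was 2.93 around the stop codon (95% interval 2.76 to 3.10, transcripts resampled), with a two-sided Fisher's exact p of 3.17e-303 and 7.92e-303 after Benjamini-Hochberg adjustment over the 5 parts. It was 1.66 in the 3' UTR (1.55 to 1.78; adjusted Fisher's exact p = 9.71e-58) and 0.541 in the 5' UTR (0.458 to 0.624; adjusted p = 2.31e-17). At the transcript start it was 0.164 (0.150 to 0.180), with a Fisher's exact p too small to be represented by the software, and 0.0992 when p and direction came from the same score version. The coding sequence had an odds ratio of 0.852 (0.805 to 0.900; adjusted Fisher's exact p = 8.25e-10), and this direction turned to 1.08 among peaks scoring above the median and to 1.19 with the strongest peak of each transcript. Without the transcript-start peaks it was 0.524. The same exclusion gave 2.17 around the stop codon, 1.21 in the 3' UTR and 0.410 in the 5' UTR. The stop-codon and 3' UTR odds ratios over all peaks thus partly reflect the low listed share at the transcript start. Within 100 nt of the transcript start 315 of 4599 peaks were listed (6.85%), against 8690 of 27410 farther away (31.7%), an odds ratio of 0.158 (0.140 to 0.177).

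The score differences, on which the list is chosen, followed the same order along the transcript, so this is not separate evidence. The median difference, test minus comparator arm, was 0.64 around the stop codon and 0.56 in the 3' UTR. It was 0.24 in the coding sequence, 0.02 in the 5' UTR and -0.33 at the transcript start (quartiles -0.77 to 0.14). The second version gave 0.88, 0.84, 0.50, 0.15 and -0.20 in these parts. In the first 50 nt the median first-version difference was -0.42 and 6.48% of peaks were listed; past 2000 nt and up to 5000 nt the median was 0.50 and 35.3% were listed.

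**Figure D2:**
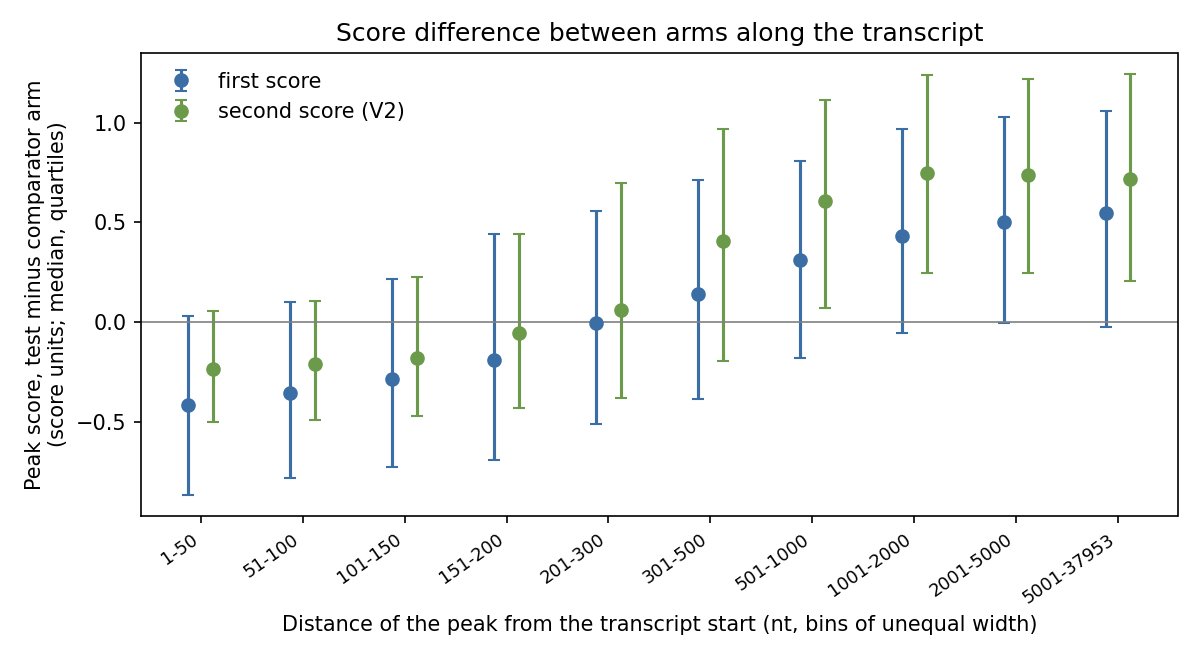
Points are median differences in peak score, test minus comparator arm, in score units (vertical axis), for peaks grouped by distance from the transcript start in nt (horizontal axis, bins of unequal width); bars span the quartiles and the colours are the 2 score versions. The first version runs from -0.42 in the first 50 nt to 0.55 past 5000 nt.

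At the transcript start more peaks met the rule in the opposite direction than were listed, 1788 of 6864 (26.0%, 25.01% to 27.1%). Around the stop codon 300 peaks (4.43%) and in the 3' UTR 219 peaks (3.95%) did so. When p and direction had to come from the same score version, 316 transcript-start peaks were higher in the test arm and 1715 in the comparator arm. Outside the transcript start the corresponding counts were 8229 and 1034.

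The table also gives a number of peaks per arm, read here as the number of replicates in which each peak was called. All replicate calls given below rest on that reading. Peaks called in all 3 test replicates and in no comparator replicate numbered 624, and the converse numbered 294. Around the stop codon these counts were 283 and 20, in the 3' UTR 128 and 11, and in the coding sequence 165 and 40. In the 5' UTR they were 12 and 13, and at the transcript start 36 and 210. A call in at least 2 of 3 replicates was recorded for 36.5% of stop-codon peaks in the test arm and 20.6% in the comparator arm. For transcript-start peaks these shares were 44.3% and 54.1%. Among listed peaks they were 39.4% and 20.5%, and among peaks outside the list 25.5% in each arm. Of the listed peaks, 5007 (55.6%) were called in more test than comparator replicates and 1386 (15.4%) in more comparator than test replicates. The list is chosen on scores from the same libraries, so these calls in listed and other peaks give it no independent support. No replicate of either arm had a call for 1339 listed peaks (14.9%) and for 16.3% of the others.

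A further question was whether METTL3-dependent peaks lay closer to a consensus motif, for which the authors' table gives a distance per peak. The table does not spell the motif out, so whether it is the motif that METTL3 methylates is not known here. Of the 9003 listed peaks with a distance, 7755 lay within 50 nt of the motif (86.1%, 85.4% to 86.8%). Of the 22998 other peaks, 16244 did (70.6%, 70.0% to 71.2%). The odds ratio was 2.58 (2.42 to 2.77, transcripts resampled; two-sided Fisher's exact p = 7.91e-198). The median distance was 12 nt for listed peaks (quartiles 4 to 30) and 24 nt for the others (9 to 60).

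The link with the motif was seen inside each transcript part. Its odds ratio was 2.49 in the 3' UTR (Fisher's exact p = 1.08e-29 after adjustment over the 5 parts) and 2.37 in the 5' UTR (adjusted p = 1.59e-06). It was 1.79 in the coding sequence (adjusted p = 2.26e-25) and 1.57 around the stop codon (adjusted p = 9.95e-10). At the transcript start it was 1.32 (adjusted p = 0.00272), where 8.62% of peaks within 50 nt of the motif and 6.67% of those beyond it were listed. Stratified by part, the Mantel-Haenszel odds ratio was 1.79 (1.66 to 1.93, transcripts resampled). Between peaks within 5 nt of the motif and those beyond 200 nt, the listed share went from 55.9% to 28.3% (16.0% to 43.5%, 46 peaks) around the stop codon and from 34.0% to 15.8% in the coding sequence. At the transcript start it went from 10.2% to 5.49%. Over all parts together it went from 41.1% to 8.35%, but 801 of the 1114 peaks beyond 200 nt, and 579 of the 6792 within 5 nt, were transcript-start peaks.

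**Figure D3:**
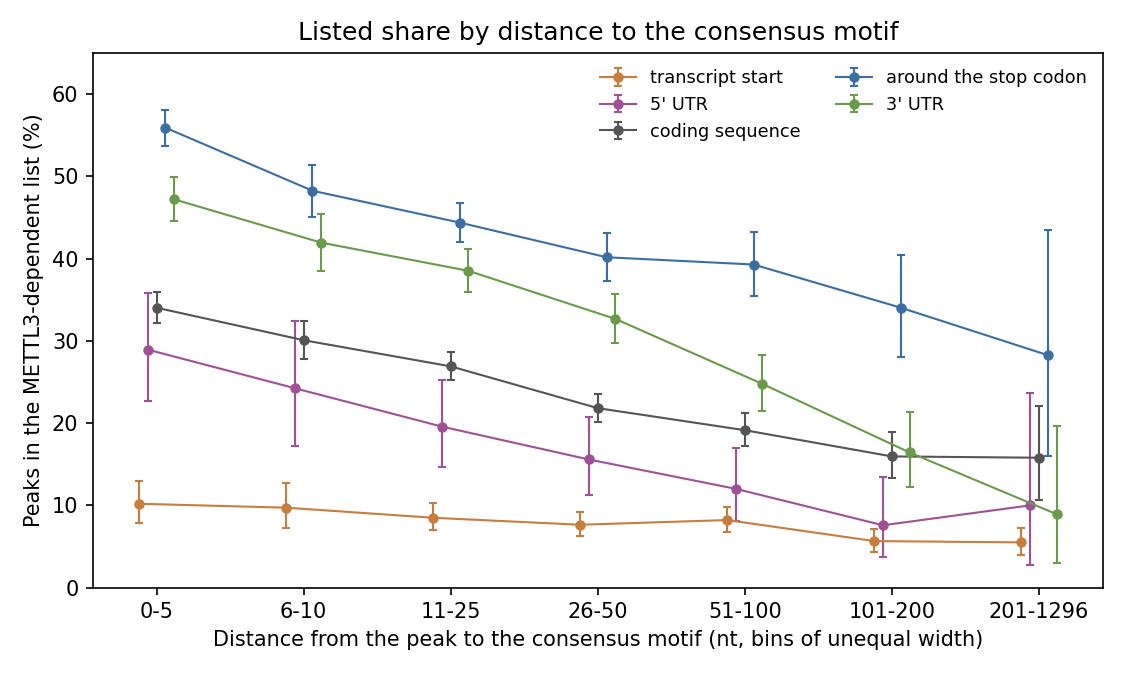
The vertical axis is the percent of peaks in the METTL3-dependent list and the horizontal axis the distance to the consensus motif in nt, in bins of unequal width; lines are transcript parts and error bars exact 95% intervals. Within 5 nt of the motif 55.9% of the stop-codon peaks and 10.2% of the transcript-start peaks were listed.

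The median test-arm score was 2.58 for METTL3-dependent peaks and 2.02 for the other peaks, a difference of 0.56. In the comparator arm the medians were 1.81 and 2.00, a difference of -0.19. On the second version the differences were 0.76 and -0.19. Membership of the list requires a higher test arm, so these differences follow the selection and no test is given for them.

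Several peaks of a transcript could be in the METTL3-dependent list. Transcripts with a peak had a median of 2 (quartiles 1 to 3, highest 20), and the 6077 transcripts with a listed peak had a median of 1 listed (1 to 2, highest 8). There were 4168 transcripts with 1 listed peak (68.6%), 1909 with at least 2 (31.4%) and 229 with at least 4. Of the 7413 transcripts with at least 2 peaks, 424 had all of them listed, 4054 had some and 2935 had none. Merging listed peaks closer than 100 nt left 8432, and the mean per transcript went from 1.48 to 1.39.

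Single peaks are given by the transcript identifiers of the table, which the name tables used here did not pair with genes, and positions are taken as mouse build mm9. In the authors' deposited table, the largest difference among listed peaks was in the coding sequence of uc009uyd.1, on chromosome X at position 166427115, with scores of 5.64 in the test arm and 0.92 in the comparator arm, unadjusted p = 0.0233 (second version 5.13 and 2.55, p = 0.0874). The authors' deposited table placed the next at the stop codon of uc007edh.1, on chromosome 1 at position 193924669, with scores of 4.17 and 0.04 and unadjusted p = 0.0121, but second-version scores of 3.76 and 2.62 and p = 0.196. The most negative difference in the authors' deposited table was at the start of uc009ipg.2, on chromosome 7 at position 108986283, with scores of -1.53 and 2.38 and unadjusted p = 0.00696 (second version 1.06 and 3.81, p = 0.0491). The authors' deposited table gave the next in the 3' UTR of uc008vtc.1, on chromosome 4 at position 147197646, with scores of -1.31 and 1.90 and unadjusted p = 0.0473 (second version 0.69 and 3.36, p = 0.0390). These 4 were chosen for their extreme differences, and each was called in at most 2 replicates of 1 arm and in none of the other.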

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

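The comparison of transcript-start peaks with the rest and the tests of weak peaks and of cap-adjacent methylation were chosen only after results were seen, while the tests of a constant offset and of different transcripts were set before theirs.

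Peaks at the transcript start moved against the rest of the transcript. The median difference in score, test minus comparator arm, of the 6864 transcript-start peaks minus that of the 25145 others was -0.74 on the first score version and -0.88 on the second, each with a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. Both values stand out as a difference between parts of the transcript under the same contrast of arms, and the medians lay on opposite sides of 0 (-0.33 and 0.41 on the first version, -0.20 and 0.68 on the second). The permutation p treats peaks as exchangeable within 1 contrast of pooled arms. It does not measure the spread between replicates, so a difference between libraries along the transcript is not excluded.

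Different transcripts at the start and elsewhere are argued against by the 3864 transcripts with both kinds of peak, since the start peak had the lower difference in 85.6% of them (84.5% to 86.7%). Weak peaks called at random would be poorly replicated, whereas 60.6% of transcript-start peaks and 29.6% of others were called in at least 2 of 3 replicates of an arm. Start peaks were thus not the more poorly replicated ones, but this test too was chosen after results were seen. A constant offset between arms cannot create a gap between parts. The medians of the weakest and strongest tertiles of start peaks differed by -0.234 (-0.282 to -0.185) on the first version. On the second they differed by 0.0839 (0.0511 to 0.116), the other way. The tertiles were set by the first-version scores that also give the first-version difference. Unequal spread in the arms could then make that trend under a constant offset, so it does not test the offset by itself. An offset added to another trend could still set on which side of 0 the start peaks lie. Methylation of the base next to the cap, which METTL3 does not make, is a hypothesis left open: the listed share was 6.48% (5.15% to 8.03%) in the first 50 nt and 12.0% (9.83% to 14.4%) between 150 and 200 nt, but this gradient was known when the test was chosen and does not count for it. Whether the explanation predicts a difference near 0 or below 0 depends on the scale of the scores, which is unknown. The listed share went on rising, to 17.4% (15.1% to 19.8%) between 200 and 300 nt and 31.8% (30.4% to 33.3%) between 500 and 1000 nt. Those distances lie beyond the transcript-start part, so methylation next to the cap alone would not account for the rise there. Whether it accounts for the start peaks themselves stays undecided. The genotype of each arm stays open too.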

How the results depend on the processing

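The alternatives by score version, a shared version for p and direction, the opposite direction, unadjusted p, an adjusted p of 0.05, unique positions and exclusion or sole use of the transcript start, and the Mantel-Haenszel analysis, were chosen after seeing the data. Of 50 alternatives, 29 kept the direction and side of the threshold or stayed within the interval or 1.5-fold of the value, 18 moved it and 3 reversed it; 25 of the 27 on position and motif kept theirs. Another 4, on the scores of listed against other peaks, are not counted, since the list is chosen on those scores. The 9005 METTL3-dependent peaks became 0 at an adjusted p of 0.01 and of 0.05 and 1 at 0.1. They became 5654 at an unadjusted p of 0.05 and 1610 at 0.01, 4533 on the first score alone (6806 on the second), 2794 on both scores and 3430 with the arms exchanged. The fewer peaks at stricter settings follow from how these are built. The median score difference of 0.25 was 0.86 among listed peaks, 0.0173 outside the list, 0.27 as a mean, 0.49 on the second score, 0.41 outside the transcript start and -0.33 at it. The listed share of 28.1% was 30.98% above the median score, 31.5% in the upper quartile, 26.7% with p and direction from the same score and 42.7% by transcript. Merging near peaks gave 1.39 listed per transcript in place of 1.48, fewer by construction. The coding-sequence odds ratio of 0.852 reversed to 1.08 above the median score (Fisher's exact p = 0.0282) and 1.19 for the strongest peak of each transcript (p = 2.77e-05), but was 0.524 without the transcript start; the cause of the other shifts was not tested. No paired analysis was possible because the deposited scores are pooled over replicates and carry no replicate number. For the same reason leaving out replicates, other normalizations, tools, pseudocounts and low-value filters were not run. Overlap matching, stop-codon windows, other motifs and gene lists were not run, since peaks are single positions without sequence or gene names. Depth is unknown, so what it limits could not be set.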

Other observations

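All tests in this part were chosen after the data were seen.

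Peaks on the X chromosome were listed less often than autosomal peaks. Of 981 X-linked peaks 226 were listed (23.0%, 20.4% to 25.8%), against 8776 of 31004 on autosomes (28.3%, 27.8% to 28.8%), an odds ratio of 0.758 (two-sided Fisher's exact p = 0.000267). Stratified by transcript part, the Mantel-Haenszel odds ratio was 0.816 (95% interval 0.681 to 0.969, transcripts resampled). The autosomes ranged from 25.4% on chromosome 14 to 30.5% on chromosome 9. Of the 8 peaks on the mitochondrial chromosome 0 were listed, which allows a share of up to 37.5% (3 counts of 8). Peaks in the same transcript are not independent, and X was singled out of the chromosomes after its value was seen.

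Among the 9005 listed peaks, 460 (5.11%) owed their low p to a score version on which the comparator arm was higher, and their direction to the other version. The rule allows, without requiring, p and direction taken from different score versions and left 0 of 32009 peaks placed differently, but it was found from the list itself, so this describes the list and tests no explanation. Of these 460 peaks, 213 lay at the transcript start (46.3%, 41.7% to 51.0%), against 316 of the 8545 others (3.70%, 3.31% to 4.12%). More comparator than test replicates had the peak called in 271 of them (58.9%). Without them, 316 of 6864 transcript-start peaks would be listed (4.60%) in place of 529 (7.71%). No biological explanation was tested for these peaks.

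The 9005 listed peaks outnumbered the 3430 that met the rule with the arms exchanged. Chance calls at an unadjusted p favour neither direction if peaks vary independently, and then the excess of 9005 over 3430 would argue against chance as the whole source. All peaks share the same libraries, however, so a chance difference between libraries can push many peaks the same way. The excess therefore does not decide this. Of the 3430 peaks, 1788 lay at the transcript start (26.0% of the peaks there) and 1642 elsewhere (6.53%), and 1189 met both rules. A shift of the test arm over all peaks could make part or all of the excess of listed peaks, and which share of the list is chance was not estimated.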
